A study of Homo sapiens with 12 samples.

How the data were processed

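Accessibility was measured by ATAC-seq in 12 libraries of human mesenchymal stromal cells, 3 for each combination of surface (flat or micropillar mPOC substrate) and medium (growth or osteogenic), prepared with a Nextera tagmentation kit. Samples were grouped by their titles, and the replicate numbers were taken from the same labels. The count table held 12 library columns and 0 columns of other samples. The series design text also names RNA-seq, which is not used here.

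The deposited count table gives whole-number read counts per region and library, without normalisation, as the values themselves show; the authors' counting tool is not stated. Per the submitters' processing notes, the tools upstream were Trimmomatic 0.39, Bowtie2, SAMtools, Picard, MACS2 2.1.0 and DESeq2, with build hg38; their roles and settings are not given in the sources used here, nor is any shift of reads to the Tn5 insertion site. The deposited peak lists, 1 per medium, give the fold enrichment of each peak over its background as MACS2 reports it. The deposited lists also give the -log10 q of each peak. How the libraries of a medium were united for peak calling is not stated. Merging both lists gave 220585 regions, and 215535 regions of the count table equalled one of them; the smallest total of a region over the libraries was 5 counts.

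Regions on chromosomes 1 to 22 and X were used (215631); others were left out of the main tests. The distance classes (promoter within 1 kb of a transcription start site, intron, distal intergenic and others) are the authors' annotation. The region's gene ID was found in the RefSeq table of GRCh38 for 215882 regions (99.9%). A region was linked to a gene for the list tests when the authors' annotation gave a protein-coding gene and the region was in a promoter class of up to 3 kb or its midpoint lay within 50 kb of either end of the gene, since strand was not given in the reference used; this linked 120437 regions, 44398 of them tested, to 14278 genes among the tested.

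Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr on the 4 groups with a smallest count of 10 left 70661 regions, 21264 of them promoters, and TMM scaling, 1 quasi-likelihood fit of the 4 groups with 8 residual degrees of freedom, two-sided F tests and Benjamini-Hochberg adjustment at 0.05 followed. The common dispersion was 0.00606, a coefficient of variation between replicates of 7.78%, and edgeR estimated an infinite prior, so the spread of every region follows the trend and a region with more spread than the trend is tested too leniently. Comparisons were pillar against flat in each medium, the difference of both (interaction), and osteogenic against growth medium on each surface. DESeq2 1.42.0 was run on the same regions. Median standard errors of the log2 changes were 0.31, 0.40, 0.52, 0.38 and 0.34 in that order. Pairs of replicates were compared by chi-square tests over regions and over 1 Mb bins. Over regions, 2 of 12 pairs, both in flat growth, had chi-square p of 0.0528 and 0.36. All 12 pairs differed over bins. Such differences cannot tell separate cultures from repeated preparations of 1 culture. All libraries were kept as replicates, as labelled.

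Of 24 gene lists fixed before the data were examined, each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison, and also with an estimated correlation and with fry. Fry tests whether a list's regions move on balance in one direction and does not compare the list with other regions. The lists were osteogenic, adipogenic, chondrogenic, extracellular matrix, focal adhesion, YAP/TEAD targets, actomyosin and SRF targets, nuclear envelope and lamina, immediate early and AP-1, glucocorticoid response, chromatin regulators, p53 and DNA damage response, cell cycle, secreted factors, TGF-beta and BMP signalling, WNT signalling, mechanosensitive channels, housekeeping, and markers of mesenchymal stromal, endothelial, haematopoietic, epithelial, smooth muscle and pericyte, and neural cells. DUSP1, CEBPD, KLF15 and ZBTB16 each belong to the glucocorticoid list and another list.

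Named genes followed a rule set at the same time: of the called, linked regions whose libraries did not overlap between groups, the 10 genes with the smallest p in each direction, each by its smallest-p region, plus up to 4 members of each list with the smallest p among those called; for the interaction, 5 in each direction without the rule on overlap. Some genes this rule picks are not reported here. Folds of regions with 1 to 3 counts in a group are given as ratios of depth-scaled counts with a 95% counting interval, and those at 0 against a floor of 3 counts over the group. Shares of counts per library were compared by exact permutation tests, region classes by Fisher's exact test against all tested regions, and peak lists with bedtools 2.31.1.

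The pipeline was tested on simulated data with the libraries' own depths and 100 changed regions per fold. It found 33% of 2-fold and 85% of 4-fold changes for pillars in growth medium, 13% and 72% for pillars in osteogenic medium, and 22% and 76% for medium on flat, and it called 1, 4 and 5 of the unchanged regions among 70661. The simulated counts were independent at 1 dispersion of 0.006, close to the fitted common value. They held no regions of extra spread and no differences over 1 Mb bins. Few false calls were thus built in, and neither they nor the shares found need hold in the real libraries. Library totals ranged from 312031 to 2508032 counts, and the median region had a mean of 3.83 counts per library.

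Alternatives were RLE size factors, library totals only, loess offsets, no filter, a mean count of at least 50, only the 6 libraries compared, the replicate number as a block, all chromosomes and contigs, leaving out each library, a 3 kb promoter window, lists linked by regions within 1 kb of a start site alone, a -log10 q of at least 5 and a reciprocal overlap of at least 50%. Robust dispersion, leaving out 42 regions whose counts spread beyond sampling noise within groups (chi-square p under 1e-10), and leaving out both shallow flat osteogenic libraries (totals under 500000) were chosen after seeing the data. So was comparing promoter regions of a list with other promoter regions in camera. GC offsets and sequence motifs are not analysed here. Further analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.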

Results

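Open chromatin was profiled by ATAC-seq, an assay in which the Tn5 transposase cuts and tags accessible DNA, in human mesenchymal stromal cells, connective tissue cells able to form bone, fat and cartilage. The cells were a commercial primary culture at passage 4, plated on flat or micropillar substrates of a polymer that the labels call mPOC, in growth or osteogenic medium, and sampled at day 1. The 4 groups, named flat growth, pillar growth, flat osteogenic and pillar osteogenic, held 3 libraries each, 12 in all. The series title states the question: how constriction of the nucleus by microtopography relates to accessibility in either medium. The pillar dimensions and the composition of the media are not given in the sources used here. The labels call the 3 libraries of a group biological replicates, and nothing says that they came from separate donors or cultures. No p-value here thus speaks for other donors or cultures. In the main edgeR fit the p-value of a region uses the spread that the trend gives, not the region's own spread between libraries. Fisher's tests run over regions, not libraries.

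The deposited count table held 215631 regions on chromosomes 1 to 22 and X, in hg38 coordinates, with a median width of 152 bp. Of these regions, 43.2% lay in introns, 26.6% were distal intergenic and 18.2% lay within 1 kb of a transcription start site. Library totals over these regions were 2305751, 2279925 and 1897476 counts in flat growth 1 to 3, and 1582153, 2139880 and 1941275 in pillar growth. They were 2508032, 446601 and 312031 counts in flat osteogenic 1 to 3, and 980559, 2502330 and 1516265 in pillar osteogenic, an 8.04-fold range. A count of 0 was found at 32.8% and 47.5% of the regions in flat osteogenic 2 and 3, at 25.0% and 19.8% in pillar osteogenic 1 and 3, and at 5.41% to 9.92% in the other 8 libraries. The limit that a count of 0 allows, 3 counts, was 1.20 to 9.61 CPM by library, so the osteogenic flat group rests largely on its first library. Intervals and floors cover counting error only. Levels below are TMM-scaled CPM (counts scaled to a common library size) as mean ± SD with n = 3 libraries per group. Regions are given as chromosome:start, and each is named after the gene to which the authors' annotation assigned it. The class of a region, such as intron or promoter, was read without the transcript that the annotation gave with it. That transcript need not be one of the named gene.

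The media differed in where the counts fell. Regions within 1 kb of a transcription start site held 40.96% ± 3.37 (SD, n = 6) of the counts in osteogenic medium and 30.7% ± 0.845 (SD, n = 6) in growth medium. The two-sided exact permutation test gave p = 0.00216, and the Benjamini-Hochberg adjusted p was 0.00866 over 12 comparisons. Introns held 29.1% ± 1.73 in osteogenic and 35.5% ± 0.484 in growth medium, and distal intergenic regions 19.0% ± 1.16 and 22.5% ± 0.310, with the same exact permutation p for each. The promoter share on pillars and flat was 43.1% ± 2.78 and 38.8% ± 2.59 in osteogenic medium (exact permutation p = 0.2). In growth medium it was 30.9% ± 0.878 and 30.5% ± 0.952 (exact permutation p = 0.6), and 3 libraries against 3 allow no p under 0.1. In a multidimensional scaling of the 500 most different regions per pair, the first dimension held 33.7% of the variation and the second 18.9%, and flat osteogenic 3 stood apart on the second.

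**Figure D1:**
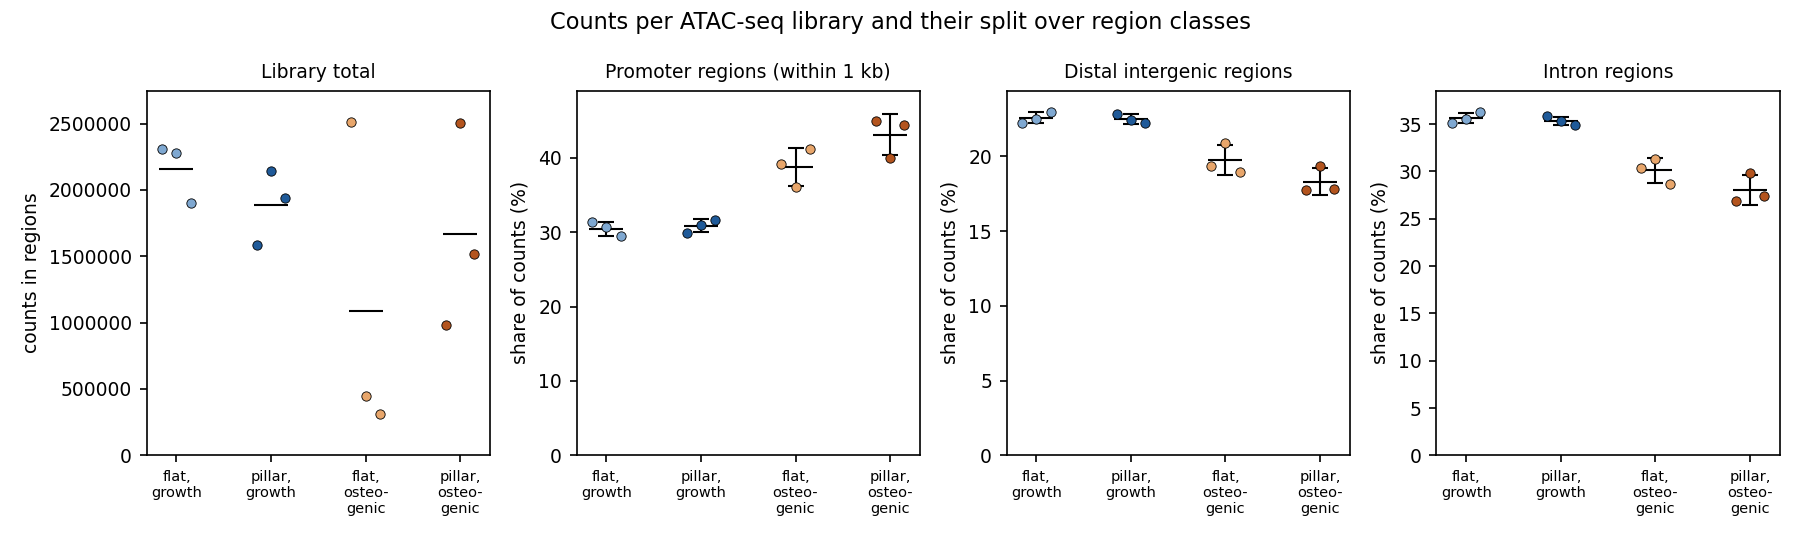
Total counts and the percentage of counts in promoter, distal intergenic and intron regions, on the vertical axes, for the 12 libraries by group on the horizontal axis; points are libraries, bars are group means and whiskers, on the shares alone, are SD. The promoter share was 40.96% in osteogenic and 30.7% in growth medium on average, while the totals spread 8.04-fold.

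The first surface comparison asked which regions opened or closed on pillars in growth medium. An intronic region of HK2, the hexokinase that starts glycolysis (2:74875002), rose from 6.89 ± 1.08 CPM on flat to 17.6 ± 0.726 on pillars (log2 change 1.32 ± 0.30 SE). A promoter region of FGFR2, a fibroblast growth factor receptor (10:121594974), rose 2.47-fold, from 7.11 ± 2.02 to 17.4 ± 2.68, while a distal FGFR2 region (10:121460850) fell from 11.7 ± 2.05 to 3.36 ± 2.1. Intronic regions of TARS3, a threonyl-tRNA synthetase (15:101684407), and of ZHX3, a zinc-finger and homeobox repressor (20:41287375), fell from 24.9 ± 4.56 to 8.96 ± 5.17 and from 12.2 ± 4.13 to 1.96 ± 1.76. By edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p was 0.027 for HK2, 0.031 and 0.033 for the promoter and distal FGFR2 regions, 7.6e-04 for TARS3 and 0.0013 for ZHX3.

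Other regions that rose on pillars lay at SSBP3, a transcription cofactor (1:54219914, log2 change 0.87 ± 0.19 SE), and at the promoter of ING4, a reader of histone methylation (12:6663086, 0.82 ± 0.19). Regions of MBOAT2, a phospholipid acyltransferase (2:9010924, 1.12 ± 0.26), LRRC30 (18:7207439, 1.60 ± 0.37) and RAPGEF6, an exchange factor for Rap GTPases (5:131680040, 2.41 ± 0.56), rose. So did RRBP1, a ribosome-binding protein of the endoplasmic reticulum (20:17666604, 1.24 ± 0.29), and LPIN2, a phosphatidate phosphatase (18:2997933, 1.27 ± 0.31). Regions that fell lay at SMIM23 (5:171757965, -1.26 ± 0.25), APCS, the serum amyloid P component (1:159598158, -1.52 ± 0.31), CHST15, a chondroitin sulfotransferase (10:123995456, -1.09 ± 0.24), and RASGRP1, an activator of Ras (15:38490230, -1.39 ± 0.31). An intronic region of PUM2, a translational repressor (2:20304498, -1.55 ± 0.35), and a promoter-class region of SUSD4, a complement regulator (1:223230621, -1.08 ± 0.25), also fell. The region with the smallest p, classed as intronic and assigned to TLL1, an astacin-type protease (4:166435474), fell by 1.23 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 4.7e-05). It was not linked to that gene by the rule used for the list tests. It lies outside the rule for named genes and was chosen after its values were seen. Of the 38 lower regions 10.5% lay within 1 kb of a start site, against 30.1% of the regions tested (Fisher's exact test, odds ratio 0.273, 95% CI 0.0704 to 0.766, adjusted p = 0.0115). Of the 18 higher ones 11.1% did (same test, adjusted p = 0.159, and 0.0373 with a window of 3 kb). These tests take regions as independent, which neighbouring regions are not, and do not cover the spread between libraries.

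In all, edgeR called 56 of 70661 tested regions on pillars in growth medium, 18 higher and 38 lower, with a median size of 1.26 on the log2 scale. An unadjusted p under 0.05 was found at 6871. In 53 of the 56 every library of one group lay above every library of the other; chance gives 10% for 3 against 3 in regions not picked for a difference, as these were. DESeq2 called 0, with 1924 at an unadjusted p under 0.05 and a smallest adjusted p of 0.763. EdgeR called 1 without the filter on low counts, 0 among the 3384 regions with a mean count of at least 50, 36 with the replicate number as a block and 243 with the 6 libraries compared alone. Without flat growth 1, 2 or 3 edgeR called 27, 9 and 11 regions, and without pillar growth 1 or 2 it called 5 and 9. Without flat osteogenic 1 or pillar osteogenic 2, which are not in this comparison but share its fit, it called 90 and 102. Of the 18 higher regions, 3 (at ANKRD26P1, MIR6724-1 and MIR4522) spread beyond sampling noise within groups.

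Few regions of the gene lists, which were fixed before the data were examined, as were the tests and the rule for named genes, passed for the surface in growth medium. An intronic region of BATF3, an AP-1 family factor (1:212693143), fell from 11.6 ± 2.32 to 2.97 ± 1.20 CPM, 1 of the 148 regions of the immediate early and AP-1 list. An intronic region of WNT7B, a WNT ligand (22:45934664), fell from 17.8 ± 0.927 to 7.05 ± 2.54, 1 of 158 regions of the WNT list. An intronic region of EPCAM, an epithelial adhesion molecule (2:47360929), fell from 31.9 ± 1.21 to 16.9 ± 0.191, 1 of 31 regions of the epithelial list. No region of the other 21 lists passed, among them the nuclear envelope, focal adhesion, YAP/TEAD target and osteogenic lists. Adjusted over the list alone, 3 regions rose and 9 fell over the 24 lists. The set test camera called 0 of the 24 lists, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.931, and fry called 0.

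In osteogenic medium a region 2 to 3 kb from a start site of FAM110B, a gene of a family of centrosomal proteins (8:58067670), rose from 3.20 ± 0.705 CPM on flat to 14.9 ± 3.12 on pillars. This 5.29-fold rise had a Benjamini-Hochberg adjusted p of 0.0086 by edgeR's quasi-likelihood test. The counts were 5, 1 and 1 in flat osteogenic 1 to 3 and 12, 32 and 13 in pillar osteogenic 1 to 3. Flat osteogenic 2 and 3 thus rest on 1 count each, below the limits of 6.72 and 9.61 CPM that a count of 0 allows there. Regions of sequence that occurs in many copies were lower on pillars: LOC101928626 at 1:633949 (log2 change -1.16 ± 0.13 SE) and 1:629859 (-0.77 ± 0.13), MTRNR2L1 at 17:22521365 (-0.93 ± 0.14) and ANKRD26P1 at 16:46390285 (-1.26 ± 0.17). The LOC101928626 and MTRNR2L1 regions lie where the nuclear genome holds copies of mitochondrial DNA, and ANKRD26P1 lies beside a centromere, as background; these 4 were chosen after their values were seen, since their libraries overlapped between groups. Counts at LOC101928626 (1:633949) ran from 855 to 1320 per library while the totals spread 8.04-fold, as the plot of repeat regions against library total shows. With both shallow flat osteogenic libraries left out, an alternative chosen after seeing the data, that group holds 1 library, which is assumed to vary like the other groups. The pillar effect then turned to 0.74 (1:633949, adjusted p = 0.0153) and 1.01 (1:629859, 7.3e-06) at LOC101928626, to 0.73 (0.112) at MTRNR2L1 and to 0.054 (0.972) at ANKRD26P1. That fit called 4 regions higher and 0 lower.

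These 5 regions, 1 higher and 4 lower, were all that edgeR called for pillars in osteogenic medium, and 5141 had an unadjusted p under 0.05. FAM110B, 1 of the 5, was without overlap between groups (10% by chance in regions not picked for a difference), and DESeq2 called 0, with 1976 at an unadjusted p under 0.05. EdgeR called 0 with robust dispersion and 1 with the regions of extra spread left out, both chosen after seeing the data. It called 0 without the filter on low counts, 1 at a mean count of at least 50, and 8 with the 6 libraries compared alone and with the replicate number as a block. The count was 137 without pillar osteogenic 2 (118 higher), 38 without flat osteogenic 1, and 2 and 3 without flat osteogenic 2 and 3. FAM110B did not pass without flat osteogenic 1 (log2 change 2.12, adjusted p = 0.446), with robust dispersion (0.0547), without the filter on low counts (0.295) or with DESeq2 (1.00). Its adjusted p lay between 0.00378 and 0.0457 under the other alternatives. No region of the 24 lists passed, and adjusted over the list alone 11 rose and 1 fell, 4 of the 11 in the TGF-beta and BMP list. Camera called 0 lists, with 4 at an unadjusted p under 0.05, the smallest adjusted p being 0.0638 for the epithelial markers, and fry called 0; with regions within 1 kb of a start site alone, camera called 9 lists against all other regions and 0 against other promoter regions.

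**Figure D2:**
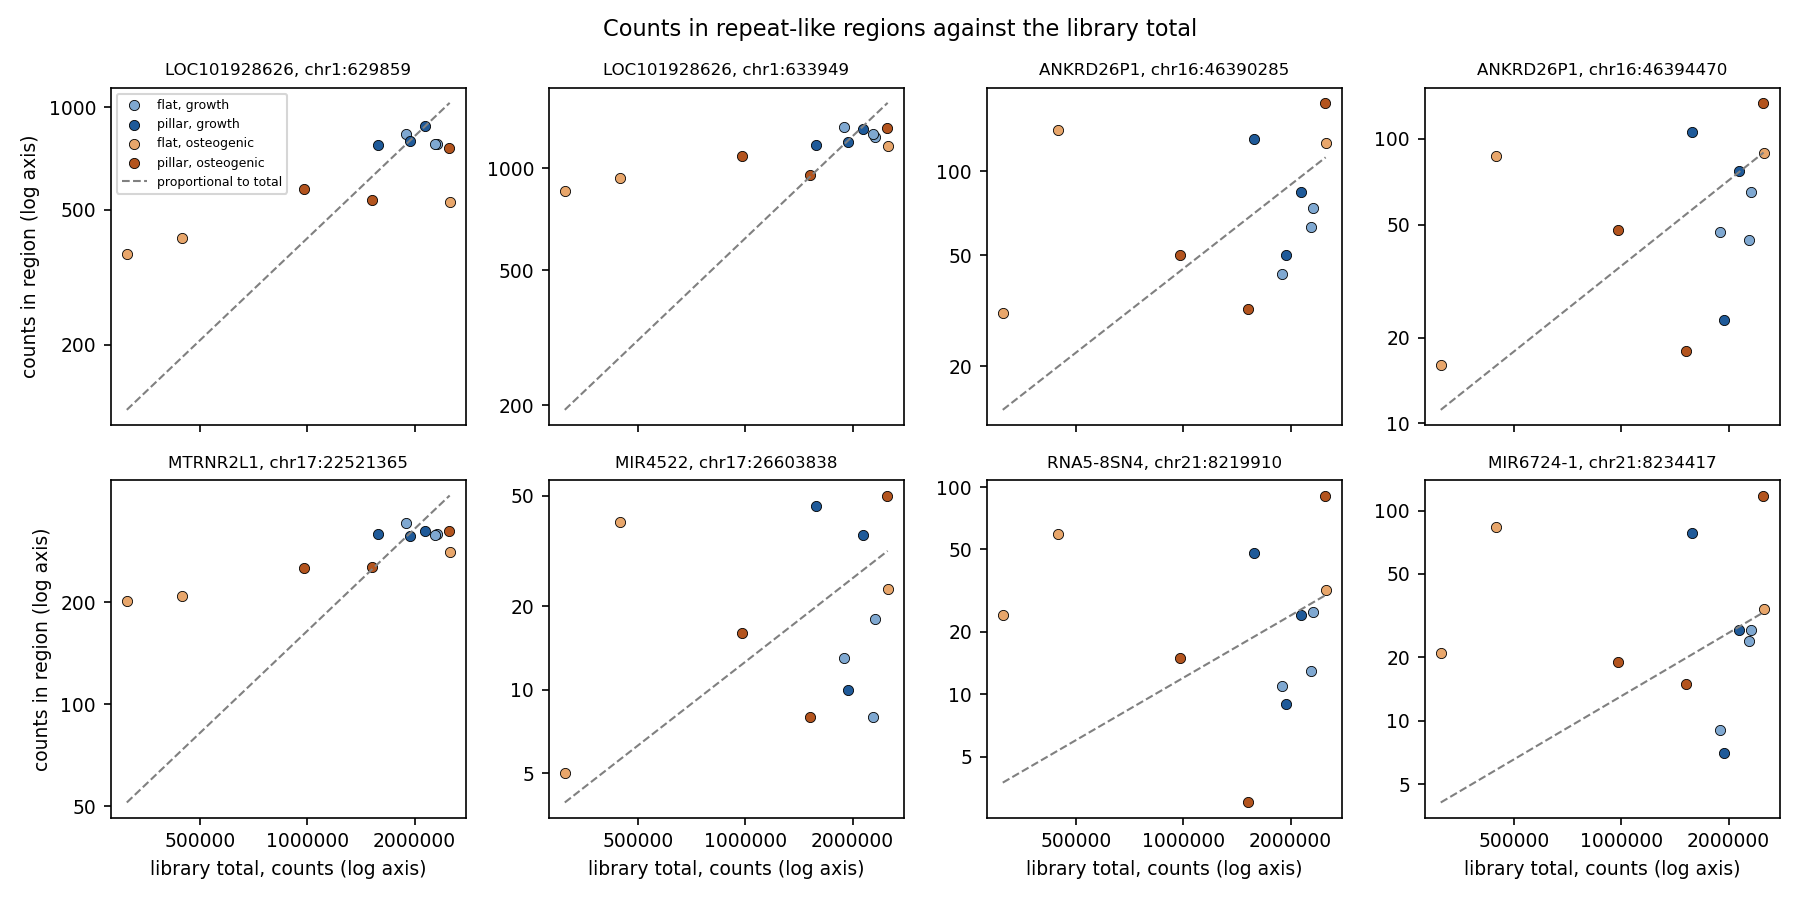
Counts on the vertical axis against library total counts on the horizontal axis, both logarithmic, for 8 regions of repeated sequence in the 12 libraries; points are libraries coloured by group and the dashed line is proportional to the total. The median slope of log count on log total was 0.219. It was 0.996 in 16199 tested regions with a mean count at least that of the lowest of the 8 and without extra spread.

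The pillar effect differed between media, by the interaction term of the same edgeR fit, at 9 regions. A region in the 3' UTR of RHBDD1, a rhomboid protease (2:226995650), went from 26.7 ± 7.28 to 13.9 ± 0.812 CPM in growth medium and from 6.53 ± 6.03 to 13.8 ± 6.97 in osteogenic medium (difference of log2 changes 2.04 ± 0.44 SE, Benjamini-Hochberg adjusted p = 0.030). Its call did not hold without flat growth 1 or 3, pillar growth 1 or 2, pillar osteogenic 2, or flat osteogenic 1 or 2 (adjusted p from 0.0692 to 0.503). The difference was 1.34 without pillar osteogenic 2 and from 1.85 to 2.5 without the others. Nor did it hold with library totals only, no filter on low counts, the replicate number as a block, robust dispersion, or with the regions of extra spread or both shallow libraries left out (difference 1.93 to 2.11, adjusted p from 0.0531 to 0.881), or with DESeq2 (2.01, adjusted p = 1.00). The other 8 regions were lower in this comparison, all in repeated sequence, at LOC101928626, MTRNR2L1, ANKRD26P1, MIR4522 and, in ribosomal DNA, RNA5-8SN4 and MIR6724-1. DESeq2 called 0 regions, and edgeR and DESeq2 had 4597 and 1496 at an unadjusted p under 0.05. Without flat osteogenic 1 or 2 edgeR called 35 and 1, without pillar growth 1 or 3 it called 5 and 17, and without pillar osteogenic 2 it called 26. It called 2 without the filter on low counts and 4 at a mean count of at least 50. With robust dispersion, with the regions of extra spread left out or with both shallow libraries left out, all chosen after seeing the data, it called 0 regions. No list passed camera or fry, with 1 at an unadjusted camera p under 0.05; with regions within 1 kb of a start site alone, camera called 3 against all other regions and 0 against other promoter regions.

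Pillar effects were compared between the media, which share no library. Of the 56 regions called in growth medium, 41 (73.2%, exact 95% CI 59.7 to 84.2) had a fold change of the same sign in osteogenic medium, 32 of the 38 lower and 9 of the 18 higher. Of the 5 called in osteogenic medium, 1 (20%) had the same sign in growth medium, and 1 region was called in opposite directions. Over all 70661 regions the fold changes had Pearson's r = 0.096. In 10 draws, simulated unchanged groups gave r from -0.0061 to 0.0056 and 44.6% to 58.9% of the same sign. These draws held independent counts at 1 dispersion, without the differences over 1 Mb bins that all 12 replicate pairs had. They cannot show what r such differences give, so whether the surface gives the 0.096 stays open. Regions are not independent replicates, so no p is given, and the CI, which takes them as independent, does not cover the spread between libraries. The share was 51.9%, 100% and 55.6% without flat growth 1, flat growth 2 and pillar growth 2, each outside that CI.

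Osteogenic against growth medium changed many more regions. A promoter-class region of ZBTB16, a zinc-finger factor induced by glucocorticoids (11:114179261), rose on flat from 1.39 ± 0.594 to 47.5 ± 4.53 CPM, 32.7-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.2e-40). On pillars ZBTB16 went from 2 to 184 counts, a ratio of 104 (95% counting interval 28.5 to 868; adjusted p = 9.9e-47). A region of COQ8B, a kinase-like protein of coenzyme Q synthesis (19:40720634), rose 18.1-fold on flat and 13.9-fold on pillars, and a region near PRPS1, a phosphoribosyl pyrophosphate synthetase (X:107674109), 14.3-fold and 10.1-fold.

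On flat, regions of DNAJB12, a chaperone of the endoplasmic reticulum (10:72334842), GPR176, an orphan receptor (15:39828734), and TOGARAM2 (2:28951947) were among the 10 higher genes with the smallest p. So were SFI1, a centrin-binding protein (22:31586209), and ABCA4, a retinoid transporter (1:93989040). Their folds ran from 8.94 at DNAJB12 to 25.9 at GPR176. Among the regions that fell on flat, an intron of RGS13, a regulator of G-protein signalling (1:192654598), went from 42.7 ± 6.40 to 7.60 ± 1.34. A region near NLRP1, an inflammasome sensor (17:5630365), fell from 57.4 ± 6.40 to 17.9 ± 3.07, and one near ELK3, an ETS repressor (12:96177058), from 28.0 ± 4.08 to 2.05 ± 1.77. Regions at FABP6, a bile acid binding protein (5:160169237, log2 change -2.07 ± 0.27 SE), F2RL1, a protease-activated receptor (5:76814212, -3.29 ± 0.43), and FBXW11, a ubiquitin ligase subunit (5:171985037, -3.71 ± 0.49), fell too. So did TMEM38B (9:105681797, -2.46 ± 0.34), ZNF672 (1:248841046, -3.04 ± 0.42) and SMIM23 (5:171757965, -2.80 ± 0.39). A NECTIN3 intron (3:111215511) fell by 2.85 on the log2 scale, a call that did not hold without flat osteogenic 1 (edgeR, log2 change -1.62, adjusted p = 0.0737). Over its other alternatives the adjusted p was at most 8.4e-04. NECTIN3 was not alone in this, since 48 of the 109 named regions for medium on flat kept their call when each library was left out in turn.

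On pillars, promoter regions of KLF13, a Krüppel-like factor (15:31365767), and CEBPD, a C/EBP factor of early adipogenesis (8:47737912), rose from 7.22 ± 2.00 to 41.8 ± 1.55 and from 18.2 ± 3.41 to 65.5 ± 4.97. Regions of PPL, a desmosomal plakin (16:4935287), FANCC, a DNA repair protein (9:95144018), APOB, the apolipoprotein of LDL (2:21038659), and DNAJB12 rose 6.44-fold, 6.26-fold, 6.26-fold and 6.92-fold. A distal region near PIK3R1, the regulatory subunit of PI3-kinase (5:68334015), fell from 39.6 ± 2.52 to 7.10 ± 2.59. Intronic regions of MAP4K4, a stress-pathway kinase (2:101887433), and DUSP16, a MAP kinase phosphatase (12:12510194), fell by 3.53 and 2.58 on the log2 scale. A region near GRB10, an adaptor of insulin receptor signalling (7:50822824), went from 48 counts to 0, at least 11.04-fold lower by the 95% counting interval (14.1-fold at a floor of 3 counts over the group). Regions at ZNF474 (5:122142389, -1.83 ± 0.23), TMEM30A, a subunit of lipid flippases (6:75275031, -2.29 ± 0.29), and ZNF133 (20:18263718, -1.85 ± 0.24) fell as well. ACSL3, an acyl-CoA synthetase (2:222919889, -2.11 ± 0.28), IQCJ-SCHIP1 (3:159082570, -1.99 ± 0.27) and DRD3, a dopamine receptor (3:114216214, -2.64 ± 0.37), fell too.

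**Figure D3:**
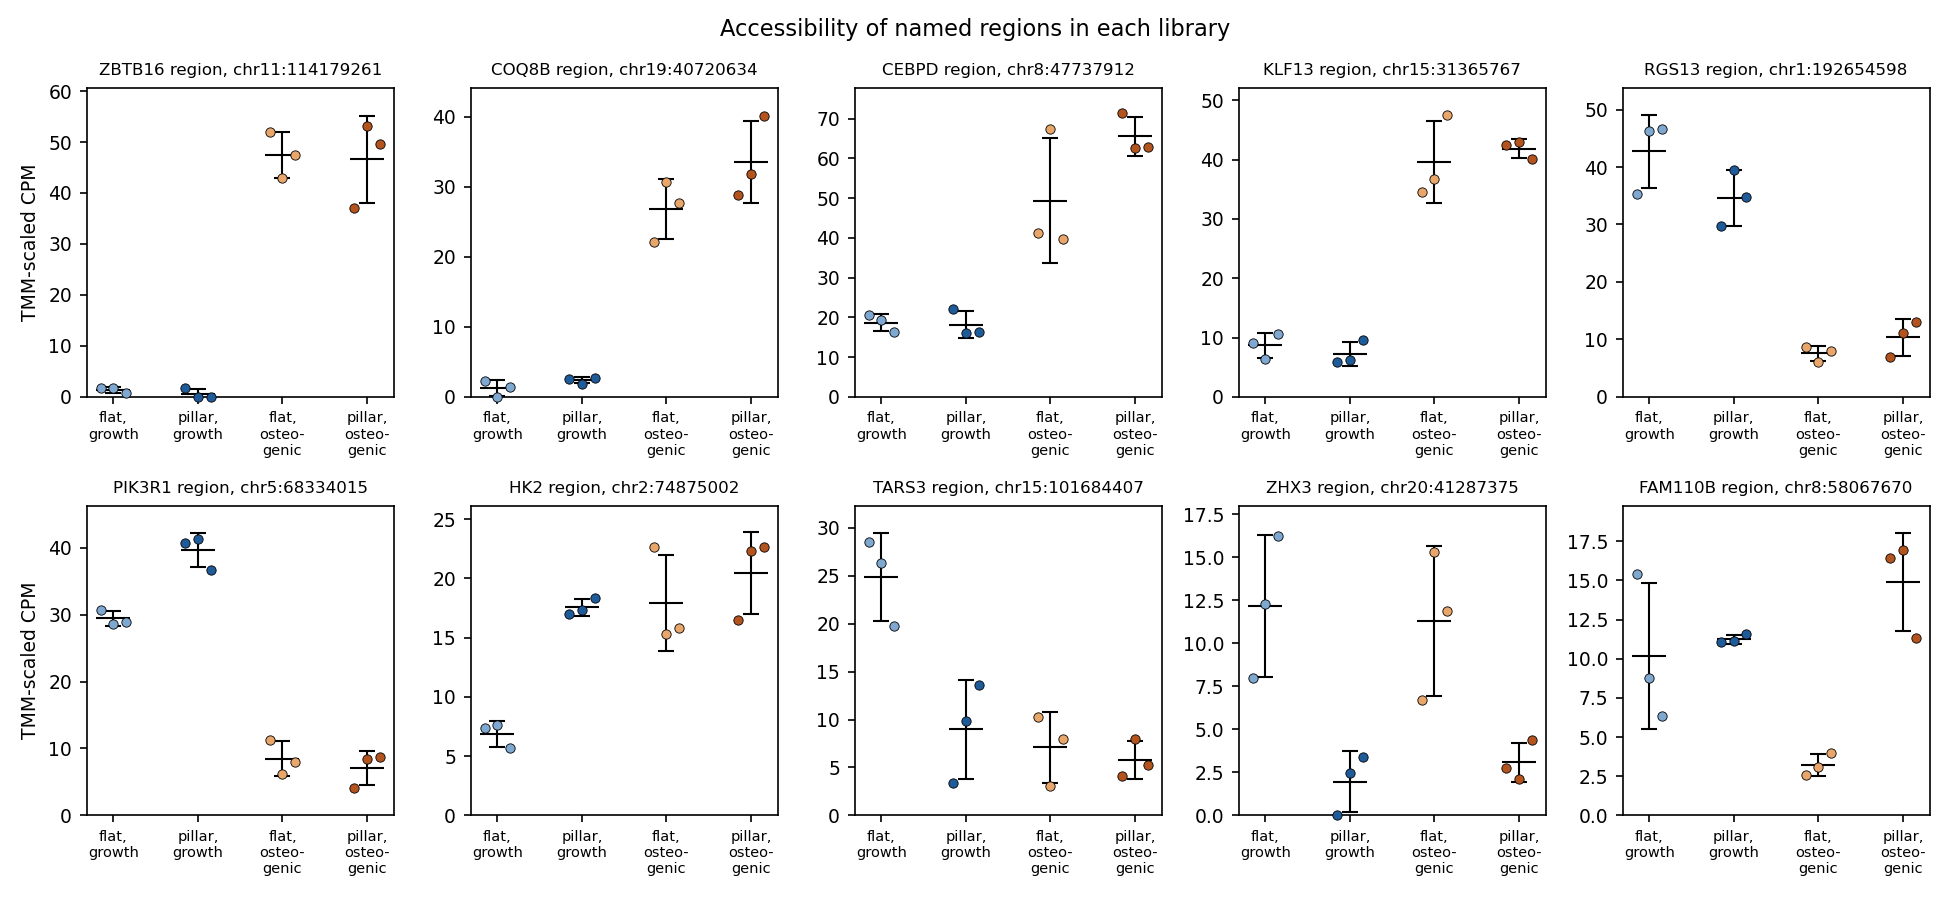
TMM-scaled CPM on the vertical axis for 10 named regions in the 4 groups on the horizontal axis; points are libraries, bars are means and whiskers SD of 3 libraries. ZBTB16 lies at 1.39 and 0.567 in growth medium and at 47.5 and 46.6 in osteogenic medium on flat and pillars, and HK2 at 6.89 on flat and 17.6 on pillars in growth medium.

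By edgeR, 15931 of 70661 regions (22.5%) differed between media on flat, 6948 higher and 8983 lower in osteogenic medium, and 24156 (34.2%) on pillars, 12187 higher and 11969 lower. The balance depended on the scaling: RLE size factors gave 5440 higher and 10760 lower on flat and 10046 and 14269 on pillars. Library totals only gave 6651 and 9455, and 10148 and 14191; loess offsets gave 7035 and 7090, and 10817 and 10707. Median sizes of the called changes were 1.28 and 1.10 on the log2 scale, and 25309 and 31359 regions had an unadjusted p under 0.05. Of the called, 12257 and 21865 were without overlap between groups; chance gives 10% in regions not picked for a difference, as these were. DESeq2 called 3728 and 10356. Without flat osteogenic 1, the only deep library of its group, the flat count was 2116, 949 of them higher; without each other library it stayed within 1.5 times. Of the regions called on flat, 97.6% had a fold change of the same sign on pillars, a comparison chosen after seeing the data. On both surfaces 4537 were called higher and 5902 lower (1198 and 1522 by chance), and 2 were called in opposite directions.

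Regions called higher in osteogenic medium lay more often at promoters than those called lower. Regions within 1 kb of a start site made up 49.3% of those higher on flat in osteogenic medium (Fisher's exact test, odds ratio 2.5, 95% CI 2.38 to 2.63). On pillars they made up 67.8% (odds ratio 7.38, 7.07 to 7.70), against 30.1% of those tested. They made up 5.10% of the lower regions on flat (odds ratio 0.106, 0.0957 to 0.116) and 5.66% on pillars (0.111, 0.102 to 0.120). Median log2 changes on flat and pillars were 0.35 and 0.52 at promoters, -0.30 and -0.36 in introns and -0.26 and -0.32 at distal intergenic regions. Neighbouring regions are not independent.

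Of the 24 gene lists, camera called the same 4 higher in osteogenic medium on flat and on pillars; counts in parentheses are adjusted over the list alone. With an estimated correlation it called 0 on flat and 2 on pillars. The number depended on the regions compared. With regions within 1 kb of a start site alone, camera called 16 lists on flat and 18 on pillars, all higher, against all other regions, most of which are not promoters. Against other promoter regions, a test chosen after seeing the data, it called 1 on each surface, the glucocorticoid response list (adjusted p = 1.8e-05 and 8.2e-07). Fry, on all linked regions, called 5 on flat, 3 higher and 2 lower, and 15 on pillars, 11 higher and 4 lower. The lower ones were secreted factors and endothelial markers on both surfaces (adjusted p = 0.0124 for each on flat), and chondrogenic genes and epithelial markers on pillars. In the glucocorticoid response list, 42 of 146 regions rose and 5 fell on flat (44 and 7), and 59 rose and 9 fell on pillars (63 and 10). A region near the start of FKBP5, a cochaperone of the glucocorticoid receptor (6:35725746), rose 17.5-fold on flat, its promoter region at 6:35727984 rose 3.56-fold on pillars, and KLF15 (3:126355907) rose 6.06-fold and 4.35-fold. Regions near TFCP2L1 on flat (2:121197369) and KLF9 on pillars (9:70418915), both transcription factors, rose 3.20-fold and 2.45-fold. Its median log2 change was 0.37 on flat (camera adjusted p = 8.8e-07; adjusted p = 0.147 with an estimated correlation) and 0.46 on pillars (camera adjusted p = 3.4e-07; adjusted p = 0.0067 with an estimated correlation).

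In the immediate early and AP-1 list, 38 of 148 regions rose and 11 fell on flat (41 and 12), and 54 rose and 18 fell on pillars (61 and 19). JUNB, a subunit of AP-1 (19:12789839), rose 2.93-fold and 2.83-fold, and DUSP1, a MAP kinase phosphatase that the glucocorticoid list also holds (5:172775548), 3.28-fold and 3.21-fold. IER5 rose on pillars (1:181105199, 2.38-fold), while a distal region of BATF3 (1:212712436) fell by 2.94 on the log2 scale on pillars. The list's median was 0.40 on flat (camera adjusted p = 3.7e-04; adjusted p = 0.147 with an estimated correlation) and 0.43 on pillars (9.3e-04; adjusted p = 0.0215 with an estimated correlation). Among promoters alone it was adjusted p = 0.0642 and 0.0584.

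Of 161 regions of chromatin regulators, 27 rose and 10 fell on flat (27 and 10), and 46 rose and 15 fell on pillars (47 and 16). A promoter-class region of KDM5A, a histone demethylase (12:334208), went from 0 to 19 counts on flat, at least 9.02-fold higher by the 95% counting interval (12.2-fold at a floor of 3 counts over the group). A region near ARID1B, a chromatin remodelling subunit (6:156731573), fell by 2.24 on the log2 scale. Promoters of HDAC1, a histone deacetylase (1:32291835), and SMARCA4, a remodelling ATPase (19:10960628), rose 2.41-fold and 2.48-fold on pillars. Of 75 regions of housekeeping genes, 10 rose and 3 fell on flat (10 and 3), and 20 rose and 1 fell on pillars (19 and 1). SNRPD3, a spliceosome protein (22:24564601), rose 7.03-fold and 4.13-fold, PPIA, a prolyl isomerase (7:44796971), rose 3.69-fold on flat, and a promoter region of RAB7A, a late endosomal GTPase (3:128794477), fell by 1.82 on the log2 scale on pillars. Medians of the chromatin regulators were 0.27 and 0.29 (camera adjusted p = 0.0352 and 0.0355; adjusted p = 0.403 and 0.19 with an estimated correlation). Those of the housekeeping genes were 0.23 and 0.45 (camera adjusted p = 0.0387 and 0.00162; adjusted p = 0.403 and 0.0865 with an estimated correlation). With loess offsets the flat values were adjusted p = 0.0568 and 0.159, and the pillar value of the chromatin regulators was adjusted p = 0.0515. Compared with other promoters, neither list's promoters were called (adjusted p from 0.878 to 0.984), and the sign was negative.

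**Figure D4:**
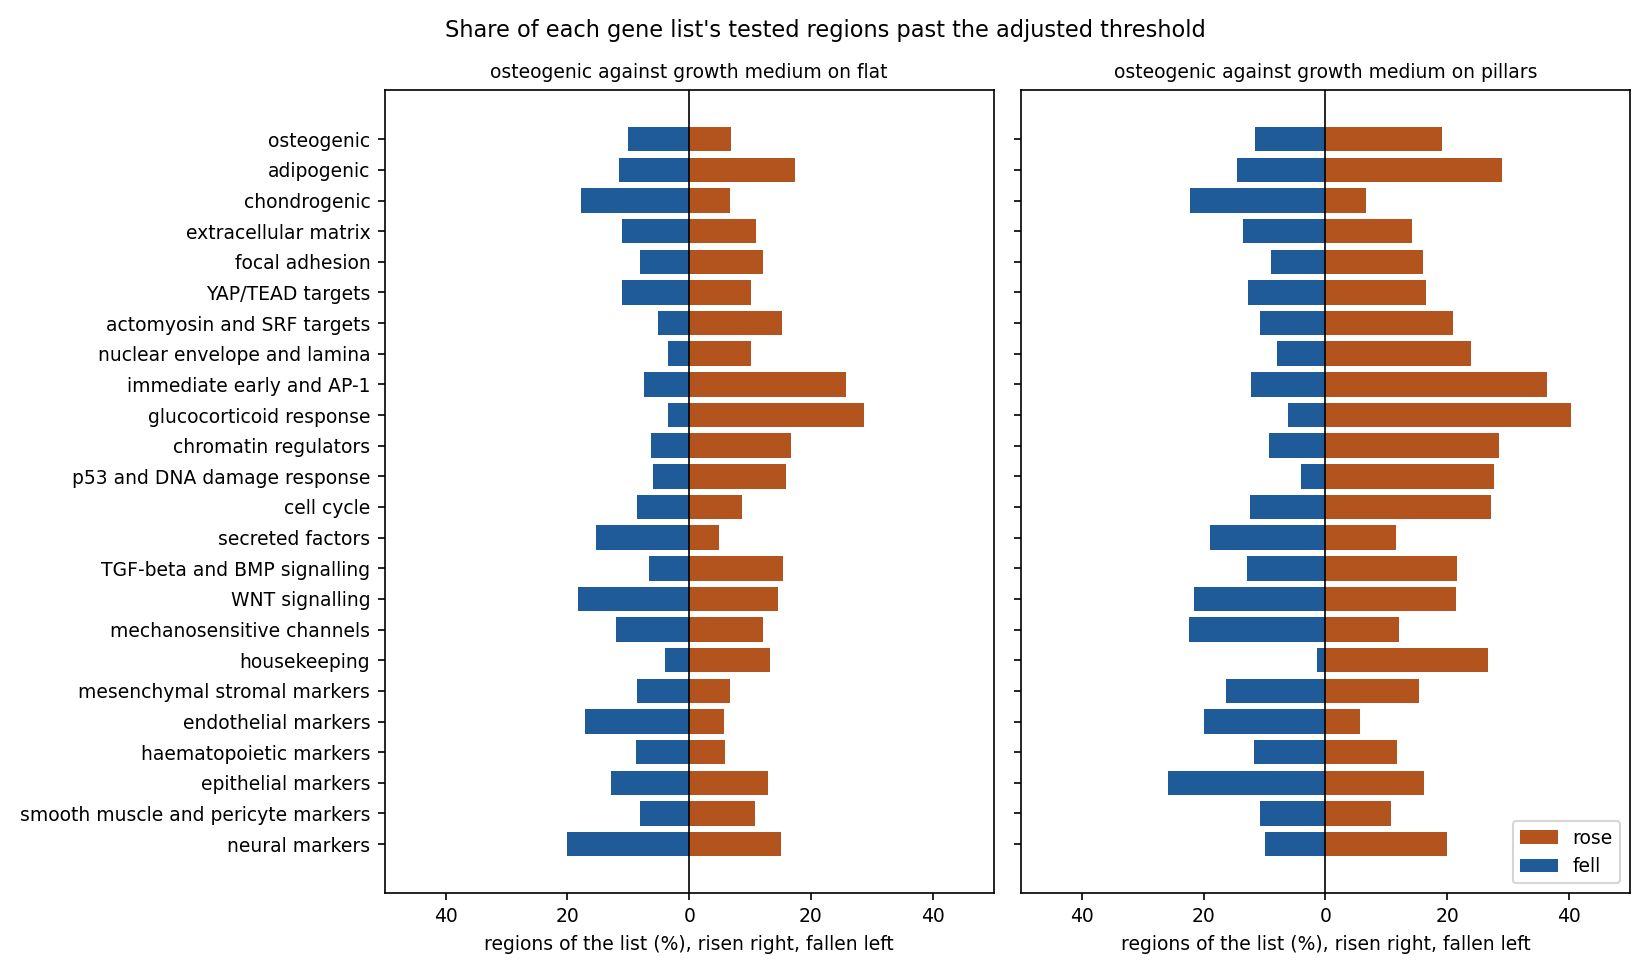
Percentage of the tested regions of each of 24 gene lists that rose (to the right) and fell (to the left) in osteogenic against growth medium, on the horizontal axis, with 1 panel for flat and 1 for pillars; bars are lists. In the glucocorticoid response list 42 of 146 regions rose on flat and 59 on pillars, and 5 and 9 fell.

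The other 20 lists did not pass camera with all linked regions, with adjusted p from 0.148 to 0.966 on flat and from 0.0599 to 0.937 on pillars, and their regions went both ways. With promoter regions alone, 12 and 14 of the 20 passed against all other regions and 0 against other promoters. Among all 70661 tested regions 6948 rose and 8983 fell on flat, 22.5% called. On pillars 12187 rose and 11969 fell, 34.2% called. Genes named below were picked by p among called members, so they do not show which way their list went. In the osteogenic list, 9 of 130 regions rose and 13 fell on flat (8 and 13), and 25 rose and 15 fell on pillars (25 and 15). On pillars ANKH, a transporter of the mineralisation inhibitor pyrophosphate (5:14871589), and FOXO1 (13:40666438) rose 2.25-fold and 2.27-fold. Of 69 adipogenic regions 12 rose and 8 fell on flat (13 and 8) and 20 rose and 10 fell on pillars (21 and 11). CEBPD rose 2.39-fold and 3.61-fold, and CEBPA (19:33302533) 2.70-fold on pillars, while LEP, the leptin gene (7:128236987), fell by 1.21 on the log2 scale there. Of 45 chondrogenic regions 3 rose and 8 fell on flat (4 and 8) and 3 rose and 10 fell on pillars (3 and 10). An intron of COL11A1, a cartilage collagen (1:102919707), fell by 1.59 and 1.74 on the log2 scale. On pillars, regions classed as intronic and assigned to ACAN, the cartilage proteoglycan (15:88881810), and SOX9, the cartilage factor (17:72126610), fell by 2.01 and 1.41.

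Among matrix and adhesion genes, 35 of 318 extracellular matrix regions rose and 35 fell on flat (34 and 35), and 45 rose and 43 fell on pillars (41 and 42). A region near LOX, a collagen crosslinking enzyme (5:122092028), went from 53 to 3 counts on flat, a ratio of 9.14 (95% counting interval 2.96 to 45.7). LOXL2 (8:23356137) fell by 1.04 on the log2 scale on flat, and the laminin gene LAMB1 (7:107972064) rose 10.9-fold on pillars. Of 224 focal adhesion regions 27 rose and 18 fell on flat (26 and 17) and 36 rose and 20 fell on pillars (36 and 19). Promoters of CAV1, the caveolae protein (7:116526145), and PTK2, focal adhesion kinase (8:141001011), rose 2.33-fold and 2.27-fold on pillars. Of 237 YAP/TEAD target regions 24 rose and 26 fell on flat (24 and 26) and 39 rose and 30 fell on pillars (37 and 29). The promoter of CCN2, a matricellular growth factor (6:131949698), rose from 69.0 ± 9.97 to 158 ± 16.5 on pillars. GADD45B (19:2478894) rose 4.60-fold on flat and 3.24-fold on pillars. A region classed as intronic and assigned to TEAD1 (11:12625734) fell by 1.95 and 2.20 on the log2 scale. Of 196 actomyosin and SRF target regions 30 rose and 10 fell on flat (27 and 10) and 41 rose and 21 fell on pillars (40 and 21). LIMK1, a kinase of cofilin (7:74142358), rose 3.33-fold on flat and the tropomyosin gene TPM2 (9:35689817) 2.94-fold on pillars.

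Of 88 regions of the nuclear envelope and lamina 9 rose and 3 fell on flat (8 and 3) and 21 rose and 7 fell on pillars (21 and 7). SUN2 (22:38755402), whose product links the nucleus to the cytoskeleton, rose 2.63-fold on flat, and on pillars SYNE1 and SYNE2, its nesprin partners (6:152111312 and 14:63852825), rose 2.89-fold and 2.59-fold and LMNB1, lamin B1 (5:126776574), 1.87-fold. Of 58 regions of mechanosensitive channels 7 rose and 7 fell on flat (7 and 7) and 7 rose and 13 fell on pillars (7 and 13). PIEZO2 (18:11178946) rose 2.83-fold and PKD2 (4:88007472) 2.71-fold on pillars. More of the list's regions fell there than rose, and its median log2 change on pillars was -0.054. Of 101 p53 and DNA damage regions 16 rose and 6 fell on flat (16 and 6) and 28 rose and 4 fell on pillars (28 and 4). SESN1, a stress-induced sestrin (6:109002103), rose 5.52-fold on flat and the death receptor gene FAS (10:88990447) 2.36-fold on pillars. Of 81 cell cycle regions 7 rose and 7 fell on flat (6 and 6) and 22 rose and 10 fell on pillars (23 and 10). PLK1, a mitotic kinase (16:23670212), fell by 1.65 and 1.81 on the log2 scale, and MCM7, a replicative helicase subunit (7:100100523), rose 1.89-fold on pillars.

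Of 163 regions of secreted factors 8 rose and 25 fell on flat (8 and 25) and 19 rose and 31 fell on pillars (19 and 30). A region near CSF2, a haematopoietic growth factor (5:132086416), fell from 21.5 ± 1.23 to 3.76 ± 3.29 on flat and from 22.8 ± 2.39 to 5.99 ± 1.63 on pillars. On pillars regions of the chemokine gene CXCL8 (4:73722000) and of IGF1 (12:102427027) fell by 2.73 and 1.93 on the log2 scale while IGF2 (11:2137274) rose 2.80-fold. Of 226 TGF-beta and BMP regions 35 rose and 15 fell on flat (35 and 15) and 49 rose and 29 fell on pillars (49 and 29). The SMAD corepressor genes SKIL (3:170356696) and SKI (1:2234443) rose 2.52-fold and 2.43-fold on pillars, and ID3, a BMP target (1:23554849), 2.68-fold. Of 158 WNT regions 23 rose and 29 fell on flat (24 and 31) and 34 rose and 34 fell on pillars (36 and 39). SFRP4, a secreted WNT antagonist (7:37907885), and APC, a scaffold that helps degrade beta-catenin (5:112684826), fell by 1.17 and 1.08 on flat, and on pillars the receptor gene FZD4 (11:86955283) rose 2.28-fold while TCF7L2 (10:112967286) fell by 2.20 on the log2 scale.

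Markers of stromal and of other cell types moved in both directions. Of 104 mesenchymal stromal marker regions 7 rose and 9 fell on flat (7 and 9) and 16 rose and 17 fell on pillars (15 and 16). On pillars the promoter of TWIST1 (7:19117405) rose 2.02-fold while an intron of PRRX1 (1:170711694) fell by 1.31 on the log2 scale. Endothelial regions that rose and fell numbered 2 and 6 of 35 on flat (2 and 6) and 2 and 7 on pillars (2 and 5). Haematopoietic ones numbered 2 and 3 of 34 (1 and 3) and 4 and 4 (4 and 4), and epithelial ones 4 and 4 of 31 (5 and 5) and 5 and 8 (5 and 8). Smooth muscle and pericyte regions numbered 4 and 3 of 37 on flat (4 and 3) and 4 and 4 on pillars (3 and 4). Neural ones numbered 3 and 4 of 20 (4 and 5) and 4 and 2 (4 and 2). On pillars TEK, an endothelial receptor (9:27094617), and EPCAM (2:47360929) fell by 1.13 and 1.39 on the log2 scale, and KRT5, a basal keratin (12:52522421), rose 3.15-fold.

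The deposited peak lists, 1 per medium, were compared without a test. The growth list held 202447 peaks with a median width of 150 bp covering 35.7 Mb, of which 54.6% overlapped a peak of the other list by at least 1 bp. The osteogenic list held 130492 peaks with a median width of 136 bp covering 21.6 Mb, of which 85.8% overlapped the growth list. In 4 of the 6 osteogenic libraries the total count was below that of every growth library, and how libraries were united for the peak calls is not given in the sources used here.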

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

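The tests on repeated sequence and of spread within groups at the regions lower on pillars were chosen after the result was seen, as was leaving out both shallow libraries; the other tests were set before. Groups of 3 libraries are too small to test a single library as an outlier. For 9 regions the pillar effect differed between media by the interaction term of the edgeR fit. The difference of the log2 changes, osteogenic minus growth medium, was -2.04 at ANKRD26P1 (16:46390285) and -1.43 at a second ANKRD26P1 region (16:46394470). It was -1.29 at LOC101928626 (1:633949), -1.0 at a second LOC101928626 region (1:629859) and -1.09 at MTRNR2L1 (17:22521365). It was -1.93 at MIR6724-1 (21:8234417), -1.84 at RNA5-8SN4 (21:8219910) and -1.99 at MIR4522 (17:26603838). At RHBDD1 (2:226995650) it was 2.04.

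The first pattern is that the 8 regions with a negative difference lie in repeated sequence: nuclear copies of mitochondrial DNA, sequence beside centromeres and ribosomal DNA. Their counts may not follow the depth of the library, since the median slope of log count on log total was 0.219 (range over the regions -0.18 to 0.35). With such a slope a shallow library would show them raised after scaling. The median slope was 0.996 in 16199 regions with a mean count of at least 22.75, the lowest of the 8. That set was not matched further on abundance and leaves out regions with extra spread. The 8 were picked by calls that set pillars against the mostly shallow flat osteogenic group, which itself favours low slopes. All 8 (100%) had counts that spread beyond sampling noise within groups, against 42 of all 70661 tested regions, with flat osteogenic 2, pillar growth 1 and pillar osteogenic 2 high together at ANKRD26P1, MIR4522 and ribosomal DNA. Without both shallow flat osteogenic libraries, which leaves 1 library there that is assumed to vary like the other groups, the difference turned to 0.59 and 0.77 at LOC101928626, 0.55 at MTRNR2L1 and 0.058 at MIR6724-1, and the other 4 stayed negative but closer to 0; one library decides nothing by itself. Both technical explanations stay open, and no biological one was tested.

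The second pattern is the gain of promoter over distal intergenic regions in osteogenic medium, a median log2 difference of 0.61 on flat and 0.85 on pillars. A higher signal over background that lifts strong regions whatever their class would leave little difference between classes matched on mean abundance. With promoter and distal regions so matched, the difference was 0.62 on flat (bootstrap interval 0.61 to 0.64) and 0.84 on pillars. This speaks to that form alone, with abundance averaged over all 12 libraries. A difference in library quality that acts unequally on promoter and distal regions was not tested and stays open. Regions picked because they were peaks in growth libraries could be high there by selection. Among regions in both peak lists the difference was 0.57 (0.55 to 0.59) and 0.80. These held 20562 of the 21264 promoter and 14844 of the 15909 distal regions tested. Leaving out so few could hardly move a median, so this test cannot decide on selection. GC content could not be matched without a genome sequence, so the difference of 0.61 over all regions may still follow it, and GC content and medium cannot be told apart here. A change of the cells with medium, which the design names, stays open and untested apart from this.

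The third pattern is that regions lower on pillars in growth medium also had lower counts in osteogenic medium: 32 of 38 (84.2%) had a negative medium effect averaged over both surfaces, while of the 18 higher ones 11 (61.1%) had a positive one, against a mean of 40.5% in matched sets with 51 of 1000 as high (53.3% and 204 without regions of extra spread). The kind of region called could account for part of it, since sets matched on class and abundance had a mean of 62.2% and a range of 36.8% to 84.2%, with 1 of 1000 sets as high. A second draw of 1000 sets gave 39.5% to 81.6% and 0 as high, so the draws leave open whether it accounts for all. Extra spread between replicates stays open too: the median within-group chi-square was 9.25, against a mean of 7.68 (range 5.50 to 10.4) in matched sets, 29 of 1000 as high. The growth libraries that picked these regions also enter the medium effect. The matched sets, drawn from regions not called, do not carry that selection, and what it adds was not tested. A shared response to surface and medium stays open as an untested hypothesis for the lower regions alone.

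Other splits of the libraries were counted for each model result. For the 3 against 3 comparisons the 10 splits are too few for a share under 0.05. The real split gave 56 regions for pillars in growth medium, where 1 of the 10 splits gave as many and the highest other gave 6. It gave 15931 for medium on flat and 24156 for medium on pillars, where 1 of 10 splits gave as many in each and the highest other gave 3 and 0. Each other split of these libraries mixes both media within its groups, so the medium effect enters the spread within groups. Few calls were thus fixed in advance, and the 3 and 0 do not measure chance. For pillars in osteogenic medium it gave 5, as many were given by 6 of 10 splits and the highest other gave 47. For the interaction the real split gave 9, 17 of 60 splits gave as many and the highest other gave 45, so chance cannot be excluded there. The 47 and 45 regions were several times the real counts. What these splits share was not tested, nor whether depth, spread above the trend or a structure of the samples other than surface gives them.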

How the results depend on the processing

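Robust dispersion, leaving out the regions with extra spread, leaving out both shallow libraries, and promoters against other promoters were chosen after the data were seen. So were the agreement of the medium effect itself, with all its alternatives, and all alternatives for the promoter share. Counts of called regions are given for pillars in growth medium, pillars in osteogenic medium, the interaction, medium on flat and medium on pillars (56, 5, 9, 15931 and 24156). DESeq2 called 0, 0, 0, 3728 and 10356 (1924, 1976, 1496, 15967 and 22316 at an unadjusted p under 0.05). No filter gave 1, 0 and 2 for the first 3 (215631 regions adjusted for), a mean count of at least 50 gave 0, 1, 4, 472 and 1196 (3384 regions tested), the 6 libraries compared gave 243 and 8 for pillars, and the replicate block gave 36 and 8; same-numbered libraries were no more alike across groups (r from -0.040 to 0.031) than others. Robust dispersion gave 0 for pillars in osteogenic medium and 0 for the interaction, leaving out regions with extra spread gave 1 and 0, and leaving out both shallow libraries gave 106 for pillars in growth medium and 0 for the interaction, with 1 flat osteogenic library that is assumed to vary like the other groups. The other alternatives stayed within 1.5 times; of the 56 regions RLE kept 56, totals only 56, loess 55, the block 36 and robust dispersion 53, and RLE moved flat medium to 5440 higher and 10760 lower and pillar medium to 10046 and 14269. Leaving out 1 library gave 5 to 102 and 2 to 137 for pillars, 1 to 35 for the interaction, 2116 to 16622 and 17846 to 24656 for medium. It gave 51.9% to 100% for the same sign of the pillar effect, 96.9% to 98.1% for that of medium, and 9.47 to 11.3 percentage points for the promoter share. The same sign of the medium effect was 97.2% with loess offsets, 98.7% at a mean count of at least 50 and 98.0% with the block. Lists past camera with regions within 1 kb alone numbered 9 for pillars in osteogenic medium, 3 for the interaction, and 16 and 18 for medium on flat and pillars; promoters against other promoters gave 1 and 1, loess left 2 on flat, an estimated correlation 0 on flat and 2 on pillars, and fry gave 15 on pillars. The share of higher growth regions near a start site was 11.1% at 3 kb too, past the threshold (adjusted p = 0.0373). Growth and osteogenic peaks shared were 54.0% and 91.1% at a -log10 q of at least 5, and 45.5% and 70.6% at a reciprocal overlap of 50%. Among promoters the lists of chromatin regulators and housekeeping genes turned negative (adjusted p = 0.984 and 0.878 on flat, 0.904 for both on pillars). RRM2B, higher with medium on pillars, went to -0.034 with loess. Without both shallow libraries the pillar effect in osteogenic medium was 0.74 and 1.01 at LOC101928626, 0.054 at ANKRD26P1 and 0.73 at MTRNR2L1, and the interaction 0.59 and 0.77 at LOC101928626, 0.058 at MIR6724-1 and 0.55 at MTRNR2L1. More regions are adjusted for without the filter, and fewer regions or libraries enter at a mean of 50 and with libraries left out; for the other changes the cause was not tested. Of the named regions, 0 of 21 for pillars in growth medium kept their call under every alternative other than leaving out 1 library, against 80 of 109 for medium on flat (48 when each library was left out in turn) and 94 of 110 on pillars (101). GC offsets, the block with GC offsets and motif searches were not run for want of a genome sequence. Depth limits most the flat osteogenic group, where 2 libraries hold under 500000 counts.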

Other observations

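Not every named region was set out in the results. In osteogenic medium on pillars, further regions rose at LGR4, an R-spondin receptor (11:27423151, 3.02-fold), WNT11, a WNT ligand (11:76251695, 5.34-fold), FBN2, a fibrillin (5:128538166, 4.22-fold), and TNS3, a tensin of focal adhesions (7:47256073, 2.95-fold), with 3 libraries per group. So did regions of CNN3, a calponin (1:94926991, 2.01-fold), FHL2, a LIM-domain cofactor (2:105398933, 2.46-fold), and FOXC2 (16:86567019, 2.74-fold). Regions that fell there were an exon of CDK6, a cell cycle kinase (7:92639454, from 13.6 ± 3.02 to 3.20 ± 0.907 CPM), a promoter-class region of FBN1 (15:48433614, from 19.2 ± 0.261 to 6.29 ± 3.21) and a region near LOX (5:122089634, from 11.9 ± 2.67 to 1.53 ± 1.94). CD44, a hyaluronan receptor, had an intronic region that rose on pillars (11:35166200, 4.95-fold). On flat, NUAK2, a kinase of the AMPK family (1:205301424), rose 2.49-fold, and the smooth muscle gene SMTN (22:31084837) rose 2.62-fold. A region classed as intronic and assigned to ZMAT3, a p53 target (3:179108120), fell by 2.08 on the log2 scale there.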
